A study of Arabidopsis thaliana with 6 samples.

How the data were processed

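RNA from whole Arabidopsis seedlings was measured on 6 two-colour oligonucleotide arrays. Per the labels' protocols, seeds germinated on MS plates or on MS plates with 10 µM copper sulphate at 23 °C with 16 h of light and 8 h of dark, and seedlings were frozen and harvested after 8 days. Total RNA was amplified, coupled to Cy5 (high Cu) or Cy3 (low Cu) and hybridised together, per the labels' protocols. The labels number 3 biological replicas with 2 technical arrays each and do not say how the biological replicas were separated, so p-values measure the spread between these 3 samples.

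Per the file headers, the images were read with GenePix Pro 6.0 at 635 nm for Cy5 and 532 nm for Cy3. Foreground and local background intensity medians are given per spot, and per the file headers each channel's intensity had been multiplied by 1 factor so that the mean ratio of medians over all features was 1. The percent of pixels above background plus 2 standard deviations and the percent of saturated pixels stand in the files as deposited by the authors. The deposited log2 ratios of the series matched the log2 of GenePix's ratio of medians for unflagged spots on each array, with a largest gap of 0.053. That comparison settles their scale as log2, their direction as Cy5 over Cy3, and their centring as GenePix's alone. The medians of the deposited log2 ratios lay between -0.016 and 0.026. Ratio of medians values below 0, where a channel lay under its background, have no log2. The labels and array files name no genome build, so no coordinates are given.

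The arrays came in 2 print versions with the same 29110 gene probes. The technical replica 1 arrays were of one version and were scanned in 2 sessions, replica 1 apart from replicas 2 and 3. The technical replica 2 arrays were of the other version and shared 1 session. This makes 3 scan sessions in all, each holding both conditions on each array. Probes were named by the locus in the files: 29023 carried a locus, of 26173 loci, and 87 named a microRNA precursor. Symbols came from the hand-written gene lists or from the RefSeq table of assembly TAIR10.1, to which 28802 probes matched; loci without a symbol keep their identifier.

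Intensities were read in R 4.3.3 with version 1.17.8 of data.table and analysed with limma 3.58.1. Background was corrected with normexp and an offset of 50, and each array was normalized by global loess, with control spots and spots with a negative flag at weight 0. Control spots and negatively flagged spots were then left out; saturated spots stayed. A probe was kept where at least 50% of its pixels were above background plus 2 standard deviations in at least 1 channel on at least 3 of the 6 arrays, which 20969 probes met. The technical arrays of each replica were averaged, and probes with values in at least 2 replicas were tested, 19669 in all. Different probes of a locus were not averaged. The log2 ratio was tested against 0 with lmFit and eBayes (n = 3, prior degrees of freedom 5.09), and p-values were adjusted by the Benjamini-Hochberg method over all probes, with a threshold of 0.05. Values are means of the replicas with their SD.

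A spot not well above background on any array in 1 channel has only a bound. The bound sets the mean of the brighter channel against that of the dimmer one, with the dimmer value on each array no lower than the lowest signal above background there. It was computed per channel after loess and Aquantile normalization. It is a mean over the replicas with no sampling error, so it is an approximate bound and not a strict limit.

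There were 24 gene lists, of which 23 had at least 3 measured members and were tested. In the list tests each locus was represented by its brightest probe with values in 3 replicas. The counts of measured genes, their calls and the medians also took probes with values in 2 replicas. Camera therefore tested fewer genes of some lists, among them 4 of 6 flavonoid, 14 of 16 iron deficiency, 7 of 9 heat shock and 6 of 9 root hair genes. The camera test of limma used a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. It found 9 lists past 0.05. With an estimated correlation, 0 lists passed, with adjusted p from 0.558 to 0.898, and 2 had an unadjusted p under 0.05. That form of the test takes its degrees of freedom from the 3 replicas, so its power is low. A list that fails it is therefore not shown to be unshifted, and its shift is left without that support. The fry test, which asks whether the genes of a list move one way on balance and does not compare them with other genes, passed 2 lists, copper deficiency and root markers, both with adjusted p = 0.034. For the replicate block and the series term, lists were tested with cameraPR on the moderated statistics.

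The lists, the design, the alternatives except those named last and the rule for named genes were set before the data were examined. The rule named 9 genes (COPT2, FSD1, CCH, CSD1, CSD2, CCS, ZIP2, FER1 and MT2A), then of each list up to 4 members past the threshold over all probes or over the list alone with the largest ratios, or up to 2 where none passed, and last the 12 raised and 12 lowered probes with the largest ratios, one sign in all 3 replicas and a locus. It gave 82 probes. RVE8, GI, COPT1, the laccase genes, COX5B-1, PAA1, PAA2, RAN1, SPL7, MT1A and SAG13 were named beyond it, after their values were seen.

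The design text of the labels calls the comparison non-paired, while both RNAs of a replica number share an array. The deviations of high and low Cu channel values from their means correlated with r = 0.79, 0.79 and 0.84 in replicas 1, 2 and 3 across 18329 probes. Sharing an array is enough for this, so it does not show that the samples were paired. The log2 ratio within an array stayed the main measure, with 491 probes passed, and the fit without the pairing passed 0.

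Alternatives covered the background correction (none, offset 0), the normalization (median centring, print-tip loess over 48 blocks, scaling between arrays), the dim filter (none, or both channels above background on all arrays), each technical series alone, a replicate block over the 6 arrays, the deposited ratios, a trended and robust variance, each replica left out, 2 other thresholds, separate channels, and for lists an estimated correlation and fry. Chosen after seeing the data were spots flagged as not found kept, either the first array of replica 1 or those of replicas 2 and 3 left out, probes with values on all 6 arrays, and the series as a term.

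The tests were tested on simulated data with the spread of the real probes. Of 19669 simulated probes, 200 were changed. limma recovered 80% of the 100 probes changed by a log2 ratio of 1 and 5% of the 100 changed by 0.5, called 7 unchanged probes and made 0 sign errors. A simulated shift of 0.3 in a list of 26 genes was called by camera, with 0 of 22 other lists called. This was a single shifted list, larger than any of the 9 lists that passed. It does not tell how often camera errs where the genes of a list are correlated. The lignin list, for one, had an estimated correlation of 0.739.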

Results

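The data compared gene expression in whole seedlings of Arabidopsis thaliana, accession Columbia, raised at 2 levels of copper. One set of seedlings grew on Murashige and Skoog (MS) plates, a standard plant medium (low Cu), and the other on the same plates with 10 µM copper sulphate added (high Cu). Seedlings were harvested after 8 days. RNA of 3 biological replicas of each condition was hybridised to two-colour oligonucleotide arrays, with 2 technical arrays per replica and 6 arrays in all. On each array the high Cu RNA carried the red dye Cy5 and the low Cu RNA the green dye Cy3. Each ratio below is high Cu over low Cu, so a positive log2 ratio means a higher signal in high Cu. The dyes were never exchanged, so a probe that takes up one dye better carries that bias in its ratio.

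Each array held 29110 gene probes. The share of probes whose spots had no negative scanner flag ranged from 38.4% to 69.9% between arrays. On the technical replica 1 arrays it was 58.7%, 42.5% and 38.4% for replicas 1, 2 and 3, and on the technical replica 2 arrays 69.8%, 69.9% and 62.5%. After the filter on dim probes, 19669 probes of 17430 loci were tested, of which 18329 had values in 3 replicas and 1340 in 2. The number of arrays limits the precision: the median standard error of a log2 ratio was 0.105.

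The technical arrays of one replica resembled each other less than arrays of different replicas scanned in one session. Across probes, which are not independent replicates, the log2 ratios of the 2 technical arrays correlated with r = 0.34, 0.17 and 0.19 in replicas 1, 2 and 3. Different replicas of the same session reached r = 0.38, 0.54 and 0.71 on the technical replica 2 arrays and r = 0.59 between replicas 2 and 3 on the technical replica 1 arrays. After averaging the technical arrays, the replicas correlated with r = 0.29, 0.36 and 0.66.

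**Figure D1:**
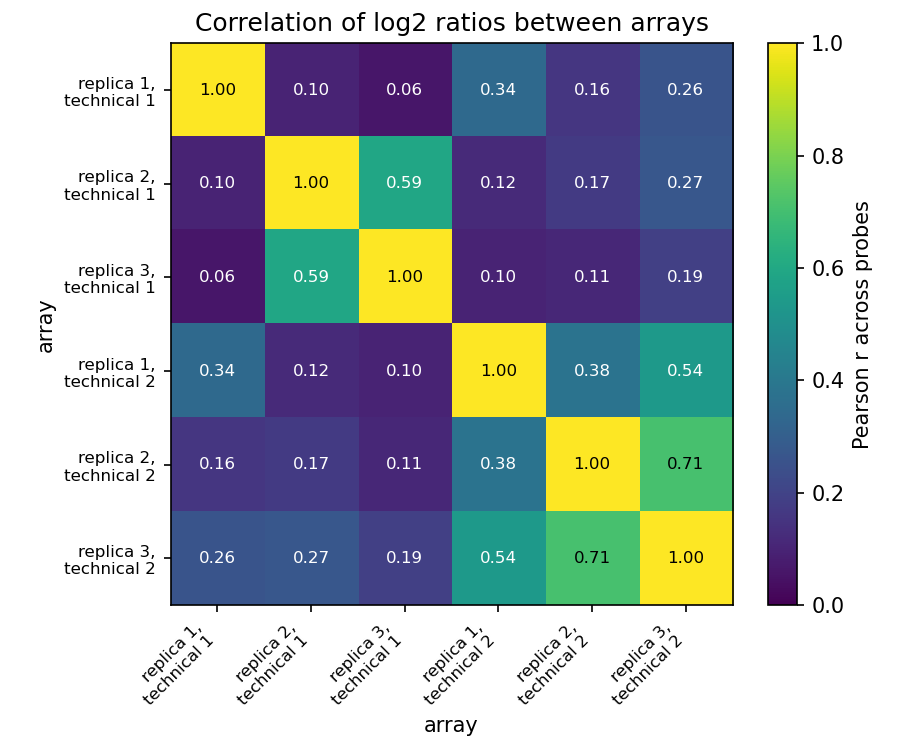
Pearson correlation across probes of the log2 ratios (high Cu over low Cu) of each pair of arrays, with technical replica 1 arrays first; colour and printed value both give r. The technical replica 2 arrays of different replicas reach 0.71, while the 2 technical arrays of one replica reach at most 0.34.

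High against low Cu asks which transcripts respond to the copper supply of the medium. A dye, labelling or scan session bias shared by the replicas would enter the same ratios and calls. Dye cannot be separated from copper here, and genes with values on the technical replica 2 arrays only come from 1 scan session. Several genes known to be active under copper shortage fell in high Cu. FSD1 (AT4G25100), the iron superoxide dismutase of the chloroplast, was 10.1-fold lower, with a log2 ratio of -3.34 ± 0.25 (SD, n = 3). The metal transporter gene ZIP2 (AT5G59520) fell to -2.19 ± 0.24, the metal-nicotianamine transporter gene YSL2 (AT5G24380) to -1.87 ± 0.07 and the high-affinity copper transporter gene COPT2 (AT3G46900) to -1.60 ± 0.24 (SD, n = 3 each). The copper-zinc superoxide dismutase genes rose: CSD2 (AT2G28190), the chloroplast enzyme, was 6.97-fold higher at 2.80 ± 0.48, and CSD1 (AT1G08830), the cytosolic enzyme, 4.30-fold higher at 2.11 ± 0.43 (SD, n = 3 each). CCS (AT1G12520), the chaperone that loads copper into these enzymes, was 4.31-fold higher at 2.11 ± 0.19 (SD, n = 3).

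Tested with limma and Benjamini-Hochberg adjustment, 491 probes passed an adjusted p under 0.05, with 258 higher and 233 lower in high Cu. They stood for 243 loci raised and 217 lowered. Of the 491, 94 changed at least 2-fold, 56 upward and 38 downward, and 480 had the same sign in all 3 replicas. The count moved with the arrays used: 51 probes passed without replica 3, 2528 without replica 1 and 350 without replica 2. Of the 82 probes chosen by the rule for named genes, 44 passed, and 21 did without replica 3. That rule favours probes that passed, so the count of 44 was partly fixed by the choice. With both series of arrays in one model, the series as a term and replica as a random block, 629 of 16803 probes passed. That model takes the arrays singly, so it may count technical arrays as replicates, here and where it is given below. Within a series, limma passed 1349 of 19419 probes on the technical replica 2 arrays and 0 of 12607 on the technical replica 1 arrays, where 1081 had an unadjusted p under 0.05. With the 2 channels as separate samples and no pairing by replicate, 0 probes passed in limma, and 608 had an unadjusted p under 0.05.

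Of the 7 measured genes on the list of copper deficiency genes, 6 fell and 0 rose, and the same 6 passed when adjusted over the list alone. COPT6 (AT2G26975), another copper transporter gene, fell to -0.67 ± 0.16 (adjusted p = 0.0253), and CCH (AT3G56240), a copper chaperone gene, to -1.61 ± 0.38 (adjusted p = 0.00678; SD, n = 3 each). The adjusted p was 0.00015 for FSD1, 0.000883 for ZIP2, 0.000798 for YSL2 and 0.00389 for COPT2. A second probe of FSD1 gave -3.23 ± 0.20 (SD, n = 3). COPT1 did not pass, at -0.20 ± 0.29 (adjusted p = 0.465). The list shifted downward against all other genes in limma's camera test with a preset correlation (median -1.61, adjusted p = 5.04e-12). It gave adjusted p = 0.558 with an estimated correlation, a form of the test with low power at n = 3. YSL2 is also known for its response to iron, and its values came from 5 of the 6 arrays.

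Of 9 measured targets of the microRNAs that plants make under copper shortage, 4 rose and 0 fell over all probes, and the same 4 passed when adjusted over the list alone. They were CSD2 (adjusted p = 0.00167), CCS (adjusted p = 0.000798), CSD1 (adjusted p = 0.00411) and ARPN (AT2G02850), the gene of the small copper protein plantacyanin, at 1.47 ± 0.40 (SD, n = 3; adjusted p = 0.00837). The laccase genes on the list did not pass: LAC4 had 0.19 ± 0.28, LAC3 -0.07 ± 0.26, LAC7 -0.26 ± 0.17 and LAC17 -0.04 ± 0.23 (SD, n = 3 each). COX5B-1, a subunit gene of cytochrome oxidase, had 0.20 ± 0.20 (SD, n = 3). The list shifted upward with the preset correlation (median 0.20, mean 0.95, adjusted p = 0.000229) and had adjusted p = 0.655 with an estimated correlation. Of the 87 probes for microRNA precursors, 1 entered the test, the MIR398b precursor, which is named here after its values were seen. It fell (adjusted p = 0.00448), with values on 4 arrays. Its high Cu channel was not well above background on any array, and the low Cu channel was above it on 5. As a mean over the replicas, high Cu was at least 2.43-fold lower, an approximate bound computed per channel, without sampling error and open to dye bias.

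Among 15 measured genes of copper transport and copper chaperones, 1 rose and 3 fell over all probes, and the counts were the same when adjusted over the list alone. The 3 that fell were COPT2, COPT6 and CCH, which the list of copper deficiency genes also holds, as it does COPT1. HMA5 (AT1G63440), the gene of a copper-exporting ATPase, rose to 0.57 ± 0.09 (SD, n = 3; adjusted p = 0.0325). The other 11 did not pass, among them the ATPase genes PAA1 at -0.07 ± 0.33, PAA2 at 0.06 ± 0.13 and RAN1 at -0.09 ± 0.27, and the regulator gene SPL7 at -0.08 ± 0.25 (SD, n = 3 each). The list shifted downward (median -0.13, adjusted p = 0.0351), with adjusted p = 0.655 with an estimated correlation. Without replica 1 its adjusted p was 0.0891, and within the 2 series it was 0.0958 and 0.0649. Without replica 3, HMA5 had an adjusted p of 0.206 and COPT6 of 0.194. Without replica 2 these were 0.0698 and 0.0581.

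**Figure D2:**
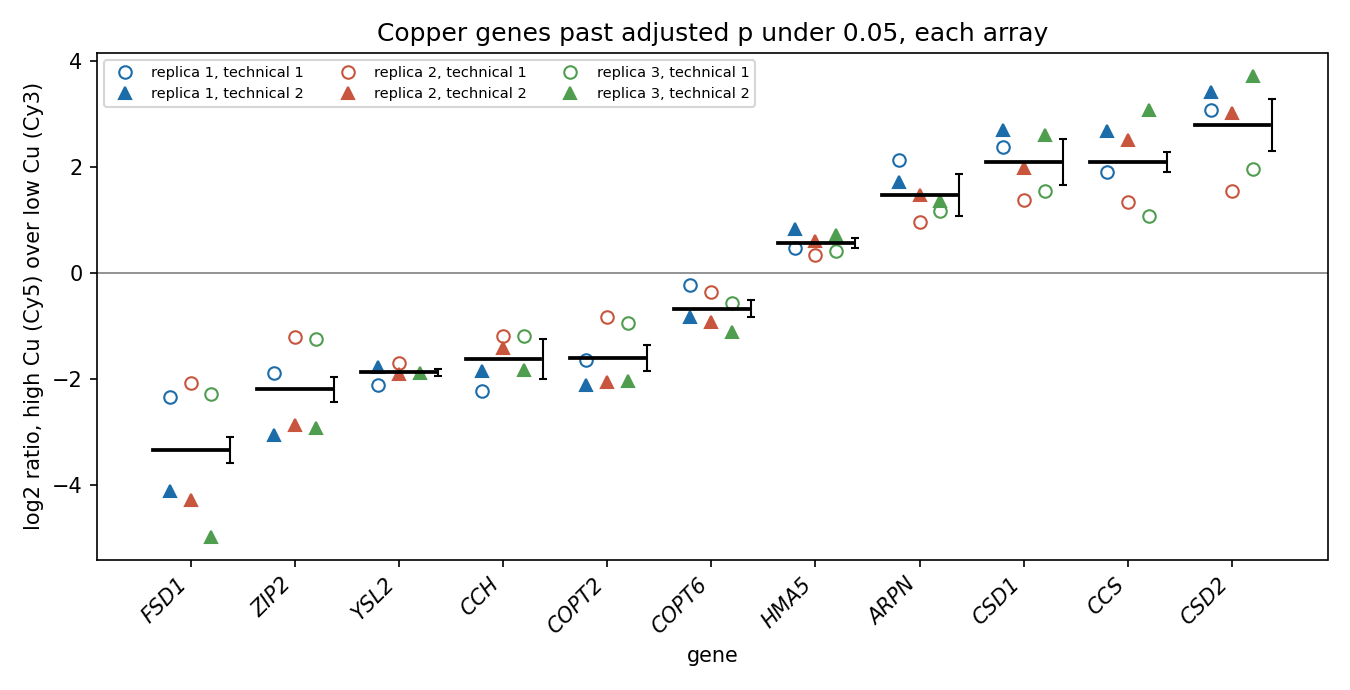
Log2 ratio of high Cu (Cy5) over low Cu (Cy3) on each array for the 11 genes of the copper lists with an adjusted p under 0.05. Open circles are technical replica 1 arrays and filled triangles technical replica 2 arrays, colours are biological replicas, black lines the mean of the 3 replicas and error bars their SD. FSD1 averaged -2.23 on the technical replica 1 arrays and -4.44 on the technical replica 2 arrays, and 10 of the 11 genes had the smaller ratio on the former.

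Of the 5 measured metallothionein genes, which encode small metal-binding proteins, MT1C (AT1G07610) fell to -0.93 ± 0.35 (SD, n = 3; adjusted p = 0.0229) and 0 rose, over all probes and adjusted over the list alone. Without replica 3 its adjusted p was 0.117. MT2A had 0.15 ± 0.17 (adjusted p = 0.503) and MT1A -0.15 ± 0.31. The metallothionein genes are alike in sequence, so a probe may take up signal from a neighbouring copy. The list as a whole did not pass (adjusted p = 0.238). Of 12 measured genes of zinc and other metal transport, IRT3 (AT1G60960) rose to 0.56 ± 0.12 (SD, n = 3; adjusted p = 0.0383), and 0 fell, with the same counts adjusted over the list alone. IRT3 had an adjusted p of 0.182 without replica 3, 0.1 without replica 2 and 0.124 with print-tip loess. It lost the call under 8 alternatives and kept it under 13. That list did not pass either (adjusted p = 0.293).

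Among 16 measured genes that respond to iron deficiency, 3 fell and 0 rose, and 5 fell and 1 rose when adjusted over the list alone. The 3 were nicotianamine synthase genes, whose product chelates iron and copper: NAS1 at -0.98 ± 0.15 (adjusted p = 0.00837), NAS2 at -0.69 ± 0.05 (adjusted p = 0.0157) and NAS4 at -0.70 ± 0.30 (adjusted p = 0.0438; SD, n = 3 each). The brighter probe of IRT1, the main root iron transporter gene, had -0.96 ± 0.56 (adjusted p = 0.0576), with values on the 3 technical replica 2 arrays only, and its second probe passed at -0.70 ± 0.26 (adjusted p = 0.037). The list shifted downward (median -0.17, adjusted p = 0.0194), with adjusted p = 0.655 with an estimated correlation, 0.31 with the series as a term and 0.769 on the technical replica 1 arrays alone (median 0.06). Without replica 3, NAS1, NAS2 and NAS4 had adjusted p of 0.0639, 0.134 and 0.247, and without replica 2 NAS4 had 0.12. With a replicate block over the 6 arrays, NAS4 had 0.0638 and the list 0.0548, and NAS4 had 0.104 with the series as a term. Of the 8 measured genes of iron storage and iron sufficiency, 0 passed over all probes in limma, 4 had an unadjusted p under 0.05 and 3 fell adjusted over the list alone. The ferritin gene FER1 had -0.59 ± 0.62 (adjusted p = 0.208). That list also shifted downward (median -0.35, adjusted p = 0.00552), with adjusted p = 0.655 with an estimated correlation and 0.368 on the technical replica 1 arrays alone.

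Of 13 measured root markers, 0 passed over all probes in limma, 8 had an unadjusted p under 0.05 and 6 fell adjusted over the list alone. The list shifted downward (median -0.30, adjusted p = 0.000229), with adjusted p = 0.558 with an estimated correlation. The median was -0.58 on the technical replica 1 arrays (adjusted p = 6.66e-05) and -0.15 on the technical replica 2 arrays (adjusted p = 0.215). PYK10, a root beta-glucosidase gene, had -0.56 ± 0.27 (adjusted p = 0.07) and CASP2, a Casparian strip gene, -0.32 ± 0.07 (adjusted p = 0.138; SD, n = 3 each). Of 9 measured root hair markers, 0 passed in limma at either threshold, adjusted or unadjusted p under 0.05, with a median of -0.03 (list adjusted p = 0.797). Of the seed storage genes, 2 were measured, SESA1 at 0.16 ± 0.12 (SD, n = 2) and SESA2 at 0.01 ± 0.07 (SD, n = 3), too few for a list test. The iron, flavonoid, lignin and sulfur lists also shifted downward, and a link between these shifts and the root shift was not tested.

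A few genes of flavonoid and lignin synthesis fell in high Cu. Of 6 measured genes of flavonoid and anthocyanin synthesis, 2 fell and 0 rose, and 5 fell adjusted over the list alone. CHS (AT5G13930), chalcone synthase, fell to -0.94 ± 0.11 (adjusted p = 0.00837) and F3H (AT3G51240), flavanone 3-hydroxylase, to -0.72 ± 0.30 (adjusted p = 0.0386; SD, n = 3 each). PAP1, a regulator of anthocyanin synthesis, had -1.34 ± 1.63 (SD, n = 2; adjusted p = 0.223). Of 11 measured lignin synthesis genes, CAD4 (AT3G19450), a cinnamyl alcohol dehydrogenase gene, fell to -0.70 ± 0.11 (SD, n = 3; adjusted p = 0.0171), 0 rose, and 4 fell adjusted over the list alone. The flavonoid list (adjusted p = 0.000229) and the lignin list (adjusted p = 0.00111) both shifted downward, with adjusted p = 0.637 and 0.68 with an estimated correlation. Neither passed with fry, with adjusted p of 0.109 and 0.325. Without replica 3, CHS, F3H and CAD4 had adjusted p of 0.0678, 0.205 and 0.111, F3H had 0.0591 with the series as a term, and without replica 1 the lignin list had 0.232. Of 13 measured genes of glutathione synthesis and sulfur assimilation, 0 passed over all probes or adjusted over the list alone in limma, and 5 had an unadjusted p under 0.05. Their list shifted downward (median -0.28, adjusted p = 0.0351), with adjusted p = 0.68 with an estimated correlation, 0.657 without replica 1, 0.385 on the technical replica 2 arrays alone and 0.0585 with a replicate block over the 6 arrays.

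Genes of the circadian clock went both ways. Of 12 measured, 4 rose and 2 fell, and 6 rose and 3 fell adjusted over the list alone. The genes that rose were PRR5 (AT5G24470), a pseudo-response regulator, at 1.71 ± 0.23 (adjusted p = 0.00265), GRP7 (AT2G21660), an RNA-binding protein under clock control, at 1.24 ± 0.67 (adjusted p = 0.0416), LUX (AT3G46640) at 0.88 ± 0.13 (adjusted p = 0.0106) and GI at 0.82 ± 0.16 (adjusted p = 0.0137; SD, n = 3 each). CCA1 (AT2G46830), a morning transcription factor, fell to -0.90 ± 0.47 (adjusted p = 0.0473) and RVE8 to -0.83 ± 0.23 (adjusted p = 0.0176; SD, n = 3 each). PRR5 had values on 4 arrays, and its low Cu channel was above background on 1 of the 6, so its fold is uncertain. The list did not pass as a whole (adjusted p = 0.0954). Without replica 3, GRP7, CCA1 and LUX had adjusted p of 0.117, 0.168 and 0.095. LUX had a value on 1 technical replica 1 array, and with spots not found kept it was at 0.38 (adjusted p = 0.126). GRP7 and CCA1 had 0.0552 and 0.0648 with a replicate block over the 6 arrays, and 0.0693 and 0.0617 with the series as a term. Both genes lost the call under 11 alternatives and kept it under 10.

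Single members of some stress and hormone lists passed. PAD3 (AT3G26830), an enzyme of camalexin synthesis, was the 1 of 9 measured salicylate defence genes that passed, at -1.12 ± 0.23 (SD, n = 3; adjusted p = 0.00837). Its mean was -1.56 on the 3 technical replica 1 arrays against 0.12 on the 1 technical replica 2 array with a value, and its adjusted p was 0.281 with the series as a term. Of 11 abscisic acid and cold genes, the dehydrin genes COR47 (0.91 ± 0.35, adjusted p = 0.0247) and ERD10 (0.62 ± 0.20, adjusted p = 0.0379; SD, n = 3 each) rose, and 3 rose and 2 fell adjusted over the list alone. Of 8 senescence genes, ASN1, an asparagine synthetase gene, rose to 0.96 ± 0.12 (adjusted p = 0.00837) and SEN1 to 0.83 ± 0.25 (adjusted p = 0.0196; SD, n = 3 each), and the same 2 passed adjusted over the list alone. The largest ratio on that list was that of SAG13, which was lower at -1.47 ± 1.94 (SD, n = 3) and did not pass (adjusted p = 0.26). Of 13 jasmonate genes, CORI3 rose to 0.90 ± 0.31 (SD, n = 3; adjusted p = 0.0199), and 3 rose and 1 fell adjusted over the list alone. The other probes of CORI3 did not pass, at 0.58 and 0.57, and its mean was 0.15 on the technical replica 1 arrays against 1.66 on the technical replica 2 arrays. Of 12 ethylene genes, 0 passed over all probes in limma, 7 had an unadjusted p under 0.05, and 4 rose and 1 fell adjusted over the list alone. The list adjusted p was 0.515 for salicylate defence, 0.651 for abscisic acid and cold, 0.0954 for senescence, 0.28 for jasmonate and 0.529 for ethylene. Under 7 of 22 alternatives the senescence list passed upward (lowest adjusted p = 0.0125), as did abscisic acid and cold under 2 (lowest 0.017) and jasmonate under 1 (0.0444). The median and mean of the salicylate list differed in sign, at 0.02 and -0.13. Without replica 3, COR47, ERD10, ASN1, SEN1 and CORI3 had adjusted p of 0.145, 0.207, 0.0604, 0.138 and 0.133, and ERD10 had 0.131 without replica 2. With a replicate block over the 6 arrays, CORI3 and PAD3 had 0.129 and 0.128, and with the series as a term CORI3 had 0.0593.

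Several lists had 0 members past the threshold over all probes in limma. Of 21 measured antioxidant and detoxification genes, 7 had an unadjusted p under 0.05 and 2 fell adjusted over the list alone, with the glutathione transferase gene GSTF6 at -0.77 ± 0.54 (adjusted p = 0.0916). Of 26 photosynthesis genes, 2 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone, with LHCB1.1, an antenna protein gene with near-identical copies, at -0.59 ± 0.28 (adjusted p = 0.0646). The median of that list was 0.05 and its mean -0.01, and with median centring in place of loess it passed upward (median 0.17, adjusted p = 0.0051), as it did without replica 1 (adjusted p = 0.017) and with spots not found kept (adjusted p = 0.0319). Of 9 heat shock genes, 3 had an unadjusted p under 0.05 and HSP23.5, at 0.71 ± 0.48, was the 1 that passed adjusted over the list alone (SD, n = 3 each). The median of the heat shock list was -0.11 and its mean 0.05. Of 9 phosphate starvation genes, 1 had an unadjusted p under 0.05 and 1 fell adjusted over the list alone, PHT1;4 at -0.52 ± 0.22 (SD, n = 3; adjusted p = 0.07). Of 9 reference genes, 0 had an unadjusted p under 0.05, with a median of 0.11 and PP2AA3 at -0.31 ± 0.33 (SD, n = 3). The list adjusted p was 0.212 for antioxidant, 0.619 for photosynthesis, 0.754 for heat shock, 0.0937 for phosphate and 0.719 for reference genes.

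**Figure D3:**
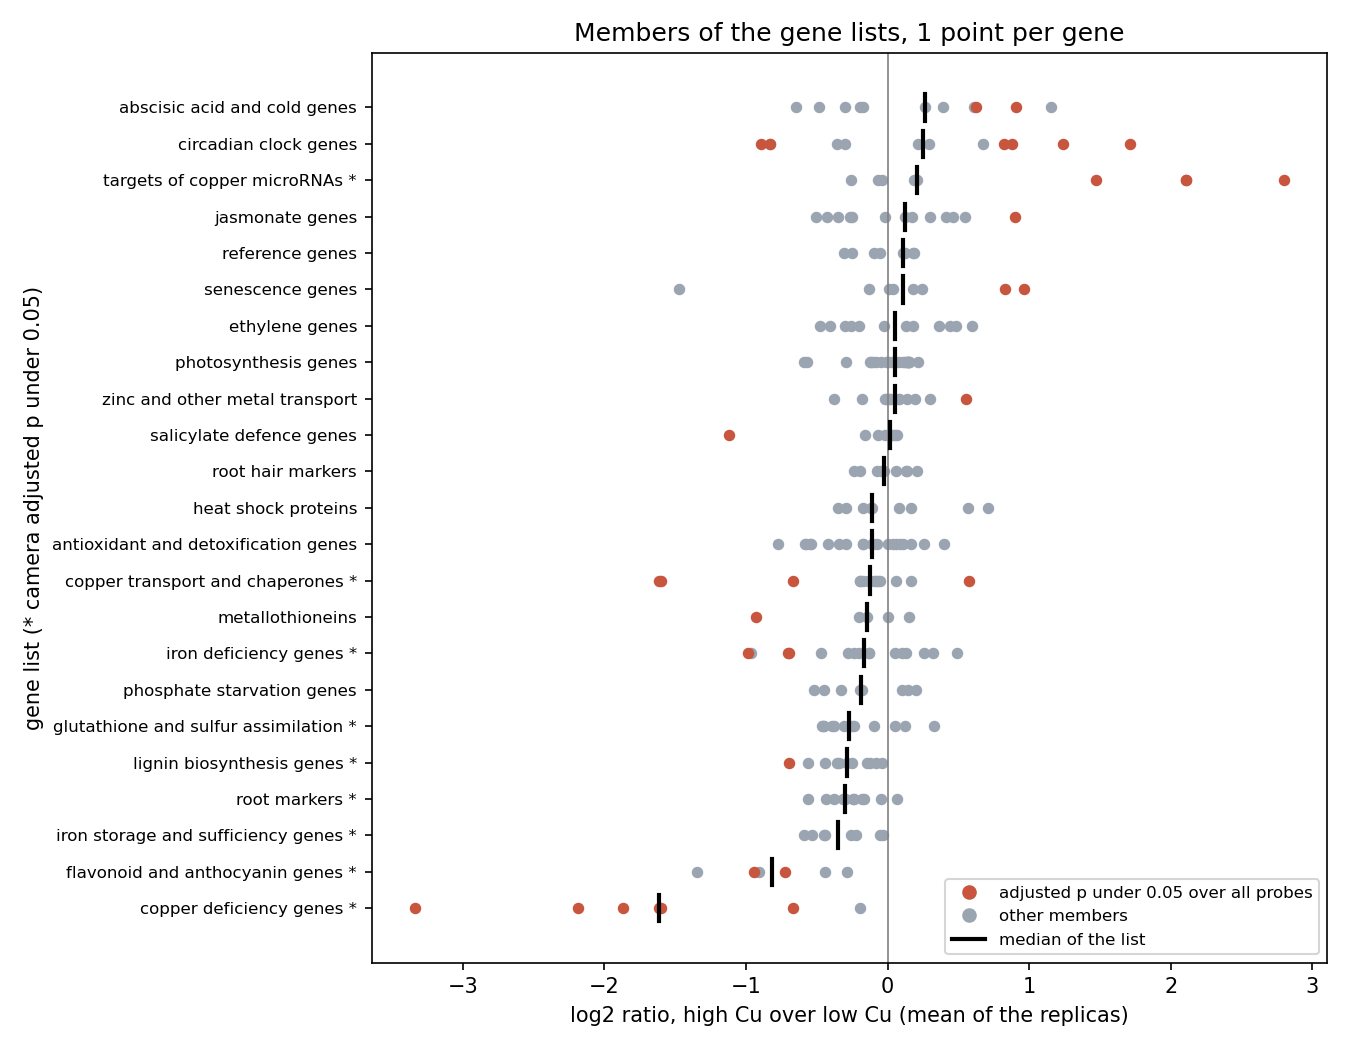
Log2 ratio of high Cu over low Cu, the mean of the replicas, for each measured member of the 23 gene lists tested, with 1 point per gene and lists ordered by their median (black mark). Red points passed an adjusted p under 0.05 over all probes, and an asterisk marks a list with a camera adjusted p under 0.05. Copper deficiency genes have a median of -1.61, and 4 targets of copper microRNAs lie between 1.47 and 2.80.

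Outside the lists, the raised genes with the largest ratios were AT2G05510, at 2.06 ± 0.13 (adjusted p = 0.000798), AT5G23700, at 1.84 ± 0.18 (adjusted p = 0.00132), and BUB3.2 (AT1G49910), a homologue of a spindle checkpoint gene, at 1.67 ± 0.15 (adjusted p = 0.00167; SD, n = 3 each). The cytochrome P450 gene CYP96A5 (1.60 ± 0.58), AT1G49570 (1.64 ± 0.37), AT2G18193 (1.56 ± 0.20), and AT2G04050 (1.52 ± 0.85) also rose (SD, n = 3 each). The low Cu channel was above background on 2 of 6 arrays for AT1G49570. It was so on 3 for AT2G05510, AT5G23700, CYP96A5 and AT2G04050, and on all 6 for BUB3.2 and AT2G18193. The folds of the first 5 are therefore uncertain. Over the alternatives, CYP96A5 ranged from 0.424 to 2.083 and AT1G49570 from 0.575 to 2.148. CYP96A5, AT1G49570 and the lowered gene AT5G48490 had values on the technical replica 2 arrays only, and AT2G04050 had -0.24 on the 1 technical replica 1 array with a value. AT3G59450 rose (adjusted p = 0.00746), and its low Cu channel was not well above background on any array. As a mean over the replicas, high Cu was at least 2.48-fold higher, a bound computed per channel and open to dye bias. It does not hold for each series: the mean log2 ratio was 0.67 on the 2 technical replica 1 arrays with values, against 1.975 on the technical replica 2 arrays. AT2G25625 fell to -2.28 ± 0.66 (adjusted p = 0.00749), while its other probes did not pass, at -0.90 and -0.97. Other lowered genes were AT5G48490 (-1.54 ± 0.26), ACA1 (AT3G52720), a carbonic anhydrase gene (-1.52 ± 0.45), AT5G37990 (-1.48 ± 0.41), AT5G38020 (-1.32 ± 0.35) and CYP79F1 (AT1G16410), which starts the synthesis of aliphatic glucosinolates (-1.43 ± 0.40; SD, n = 3 each). The other probes of ACA1, at -1.16 and -0.93, and of CYP79F1, at -1.19 and -1.03, fell as well. CYP79F1 has a close copy, CYP79F2, and its probes may take up signal from it. Without replica 3, ACA1, AT5G37990, CYP79F1, AT5G38020 and AT2G04050 had adjusted p of 0.0628, 0.0582, 0.0582, 0.0609 and 0.149. AT2G04050 had 0.109 with a replicate block over the 6 arrays and 0.0585 with the series as a term.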

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

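The 3 tests on the grouping of the arrays were chosen after the result was seen; the other tests of this part were set before theirs.

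For 6 of the 46 named probes with values on all 6 arrays, 1 array lay far from the others, and each time it was the technical replica 1 array of replica 1. Chance gives about 5% of such groups. FER1 had a log2 ratio of -2.08 there against -0.64 to 0.16 on the other arrays, LHCB2.1 had -2.02 against -0.65 to -0.01, and 4CL1 had -1.58 against -0.55 to 0. PYK10 had -1.47 against -0.53 to -0.24, YSL1 had -1.23 against -0.58 to -0.28, and PHT1;4 had -1.12 against -0.48 to -0.35. On the first principal component, with 46.2% of the variance, this array lay at -45.9 and the others between 0.2 and 16.1. Without it, 895 probes passed in place of 491.

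Control spots named Alien, which the comparison does not use, were above background more often than empty spots on all arrays. On the technical replica 2 arrays they were above background in 79.3%, 80.4% and 65.2% of cases for replicas 1, 2 and 3, against 9.35%, 9.65% and 8.82% of empty spots on the same arrays. On the technical replica 1 arrays the Alien spots were above background in 13%, 15.2% and 21.7% of cases, against 1.06%, 0.98% and 1.13% of empty spots. The pattern was not particular to Alien spots. Control spots named atc were above background in 76.4%, 72.2% and 64.6% of cases on the technical replica 2 arrays. For the same replicas they were so in 6.25%, 5.56% and 4.86% on the technical replica 1 arrays.

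Arrays of different replicas within a scan session correlated with a mean r of 0.56, against 0.23 between technical arrays of one replica. On the technical replica 1 arrays, of one print version, replica 1 was scanned apart and had r of 0.1 and 0.06 with replicas 2 and 3, so the print version alone does not group the arrays. Exchanged replica numbers on one series stay open: the best of the 6 ways to match the numbers exchanges replicas 2 and 3 and reached a mean r of 0.24, against 0.23 as labelled, and a difference between sessions holds every such r low. Noise of dim spots is argued against, since probes above the upper quartile of intensity gave 0.23 between technical arrays and no less than 0.41 within a session. Scan session, and the labelling that may have gone with it, stay open, and no biological explanation was tested.

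Of the 11 called copper genes, 10 had a smaller ratio on the technical replica 1 arrays, where the mean absolute log2 ratio was 0.641 of that on the technical replica 2 arrays. Of all called probes with values on both series, 240 of 424 were smaller there, with a slope of 0.74. An offset of 0 left the ratio of the copper genes at 0.646 and median centring at 0.641, so neither the background offset nor the loess fit accounts for it. Saturated spots are argued against, because 0 of the 11 genes had a saturated pixel on a technical replica 1 array. The genes were picked from a mean of both series, and what differs between the print versions or the labelling may still set the size, so the folds carry that uncertainty.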

How the results depend on the processing

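The alternatives chosen after seeing the data were those with spots not found kept, with first technical arrays left out, with the series as a term, and with values on all 6 arrays. No named probe past the threshold turned its sign. Of the 491 probes, 476 kept their sign with spots not found kept, and 267 of 268 and 483 of 484 measured on the technical replica 1 and 2 arrays alone; elsewhere all measured did. These arrays also entered the calls, so signs are partly shared by construction. The median of the iron deficiency list turned from -0.17 to 0.06 on the technical replica 1 arrays alone. The count of 491 stayed within 1.5 times (340 to 706) under 11 of 23 alternatives, among them each background correction and normalization, the deposited ratios (396) and the replicate block over 6 arrays (543). That block gave 7 lists and 42 named probes, but its estimated correlation of technical arrays was -0.112, so it does not guard against counting technical arrays as replicates. The fit without the pairing, with separate channels and no replicate block, passed 0 probes and 0 named probes in limma (608 with an unadjusted p under 0.05), and the spread between arrays enters the error there by construction. The count was 94 with a fold of at least 2, 1098 at an adjusted p under 0.1, 132 of 8577 probes with both channels above background on every array and 187 of 10233 probes with values on all 6 arrays, where fewer probes were tested. It was 0 on the technical replica 1 arrays alone (1081 with an unadjusted p under 0.05) and 1349 on the technical replica 2 arrays alone. It was 895 without the first technical array of replica 1 and 872 without those of replicas 2 and 3, and 3572 with spots not found kept, of which 12.3% were raised against 52.5%, with the median of all probes at -0.11. Leaving out each replica gave 51 to 2528. The cause was not tested except where given.

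Of the 82 named probes, 44 passed, a count partly fixed by the rule, which favours probes that passed. This became 19 of 39 measured with both channels above background, 26 of 46 with values on all 6 arrays, 69 with spots not found kept, and 0 of 58 on the technical replica 1 arrays alone, and leaving out each replica gave 21 to 60. For single named probes, 1356 comparisons stayed on their side of the threshold, 154 lost the call and 84 gained one. Of the 9 lists called by camera, 0 passed with an estimated correlation and 2 with fry. Leaving out each replica gave 10 to 11 lists, not all of them among the 9. For single lists 438 comparisons stayed, 43 lost the call and 20 gained one; the metallothionein, zinc, antioxidant, heat shock, phosphate, clock and root hair lists each gained 1. Signal over background limited the technical replica 1 arrays of replicas 2 and 3, whose median Cy5 signal was 40 and 28 against 297 and 194 on their technical replica 2 arrays.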

Other observations

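The clock, DNA damage and glucosinolate lists of this part were written after the leading genes had been seen, with PRR5, GRP7 and FKF1, the DNA damage genes that led, and CYP79F1 left out; each test was set before its result was seen, and the tests by series of arrays were chosen after.

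Genes of aliphatic glucosinolate synthesis, the pathway of methionine-derived defence compounds, were lower in high Cu. Of 16 measured, 11 fell and 0 rose over all probes, and 14 fell adjusted over the list alone. MAM1, of the chain elongation step, fell to -1.09 ± 0.55 (adjusted p = 0.0375), IMD1 to -1.07 ± 0.38 (adjusted p = 0.0176), CYP83A1 to -1.01 ± 0.13 (adjusted p = 0.00808) and the flavin monooxygenase gene FMOGS-OX3 to -0.93 ± 0.22 (adjusted p = 0.0123; SD, n = 3 each). The regulator MYB28 did not pass, at -0.33 ± 0.19 (adjusted p = 0.177). The hypothesis of lower aliphatic glucosinolate synthesis was tested with camera: p = 2.45e-16 with the preset correlation and a median of -0.83, p = 0.0536 with an estimated correlation, and p = 1.49e-06 and 2.85e-12 on the technical replica 1 and 2 arrays. The list was prompted by CYP79F1, a gene of this pathway that led in these same data. The genes are co-regulated, so leaving CYP79F1 out does not make this a separate test. Both series hold the same biological replicas, so their p-values do not replicate each other. A few samples may set all these genes, and no other explanation was tested.

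A response to DNA damage is a hypothesis for some raised genes. Of 17 measured genes on that list, 3 rose, SMR7 at 0.75 ± 0.26 (adjusted p = 0.0296), TSO2 at 0.69 ± 0.30 (adjusted p = 0.0441) and MND1 at 0.67 ± 0.11 (adjusted p = 0.0195; SD, n = 3 each), while 8 rose adjusted over the list alone. BRCA1 did not pass, at 0.38 ± 0.21 (SD, n = 3; adjusted p = 0.135). The camera p was 0.000101 with the preset correlation, 0.0541 with an estimated correlation, and 0.00121 on the technical replica 2 arrays. Genes seen in these same data prompted the list, so this is no fully separate test. The criterion set beforehand, a camera p under 0.05, was met, and the result was set back to open after the arrays were tested by series. On the technical replica 1 arrays the p was 0.719 with a median of 0.00, so the shift may belong to one array series and stays open.

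A candidate explanation for the clock genes, which is left open, is that the 2 sets of seedlings were at different times of the day at harvest. Genes written down as evening-phased (7 measured) had a median log2 ratio higher by 1.09 than those written down as morning-phased (5 measured). Most of them belong to the clock list whose results had been seen, so this is no separate test. Those written down as evening genes but outside that list were mostly negative: BBX25 had -0.73 ± 0.39, CDF1 -0.51 ± 0.17, BBX24 -0.17 ± 0.27 and GRP8 0.27 ± 0.17 (SD, n = 3 each, 2 for CDF1). Phases were assigned by hand and not checked, and those of BBX24, BBX25 and CDF1 are in doubt. The fall of these genes is therefore not weighed against a different time of day. The gap of 1.09 and the medians below also rest on these phases. On the technical replica 1 arrays the evening and morning medians were 0.02 and -0.53, and on the technical replica 2 arrays 0.47 and -0.75. The median of the raised clock genes was 0.85 without replica 1 and 1.24 in it. These genes were called from the mean of all 3 replicas, so a high value without replica 1 was partly fixed by the choice. This cannot decide whether replica 1 was the sole source, and harvest times are not given in the labels.

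The count of 491 probes was set against the other ways of giving the 3 replicas a sign. There are 4 such ways, too few for a share under 0.05; the real one gave 491 and the highest other 0. AT3G56230, the neighbour of CCH in the annotation, fell to -1.13 ± 0.40 (SD, n = 3; adjusted p = 0.0161), named after its values were seen.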
